A study of Mus musculus with 9 samples.

How the data were processed

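Liver RNA of 9 male C57BL/6 mice was sequenced as 9 libraries, 3 for each of 3 diets that differed in iron content. According to the sample protocols, RNA was isolated with RNeasy Mini columns, libraries were made with the Illumina TruSeq RNA kit and sequencing was done on an Illumina HiSeq instrument. The deposited values are raw counts of reads per gene symbol, 1 table per library, with 23420 genes and 5 category entries at the end of each table. The submitters' processing notes name FastQC and the builds mm10 and mm9 without giving the role of either build, and the tables hold no coordinates. The aligner, the counting program, its version and its strand setting are not given in the sources used here. The category entries show that reads aligned to several places, and reads overlapping several genes, were left out of the gene counts. Counts of close paralogs (Hamp and Hamp2, and members of the Cyp4a, Cyp2c, Gsta, Gstm, Mup, Ces and Acnat families) are therefore uncertain, and overlapping or antisense genes cannot be told apart without the strand setting.

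Gene reads per library ranged from 22 M to 33.8 M, 245 M in all. Reads outside any gene made up 13.4% to 25.9% and ambiguous reads 0.477% to 0.917% of the uniquely aligned reads. A further 27.5 M to 55 M alignments per library were not unique. The category entries were left out of library sizes and of every test. Intervals for shares of reads are Wilson 95% intervals and cover counting error only.

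The counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few reads were removed with filterByExpr, which left 13020 genes, and 5625 genes had no read in any library. Library sizes were scaled by TMM. CPM values were computed by edgeR on the scaled library sizes, and log2 CPM values used a prior count of 2. A quasi-likelihood model with robust dispersion was fitted to all 9 libraries with diet as the only term, and F-tests gave the 3 pairwise comparisons and a 3-group test. A second model used log10 of the dietary iron content as a number. P-values were adjusted by Benjamini and Hochberg over all tested genes within each comparison, with 0.05 as the threshold. SE is the standard error of a log2 fold change, computed from the fold change and its F statistic. Common biological variation (the square root of the dispersion) was 0.177.

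The work drew on 40 gene lists, of pathways and of cell type markers. In each pairwise comparison the 39 lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The pancreas markers had 1 tested member and were not tested. For each list, the number of members past the threshold is given over all tested genes and adjusted over the list alone. Camera p-values were adjusted over the 39 lists.

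Genes were named by rule. The rule takes a panel of 14 iron genes whatever their result. It takes, per pairwise comparison and direction, the 10 largest changes among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, or the 3 lowest p-values where fewer than 3 qualify. It also takes up to 4 members with the lowest p of each list described, the 5 lowest p-values of the 3-group test and the 5 lowest in each direction of the trend. Predicted gene models and pseudogenes were counted but not named among the largest changes. The groups, tests, gene lists, naming rule and most alternatives were set before the data were examined.

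The alternatives were other thresholds, no filter and a filter at 1 CPM in 3 libraries, DESeq2 size factors and upper-quartile scaling, DESeq2 1.42.0, limma-voom with and without sample quality weights, a fit of the 6 compared libraries alone, and each library left out in turn. Genes to which DESeq2 gives no p-value stayed without one. Alternatives chosen after the data were seen were the title number of each library as a covariate, consecutive title numbers as a block, 2 pairs of libraries left out, and the genes Rn45s and Lars2 left out. Other splits of the libraries were counted for each gene-level result, all 10 for each pair of diets and 100 for the 3-group test and for the trend.

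The model was tested on simulated data with 200 changed genes per comparison. It recovered 70% to 77% of the genes changed 2-fold and 92% to 99% of those changed 4-fold, and 10 to 13 of its 177 to 187 calls were unchanged genes. Camera called both changed lists and 0 of 38 unchanged lists in each pairwise comparison. The simulated genes were drawn independently of each other, and only genes with a mean of at least 1 CPM were changed. Variation that many genes of a library share was left out. The recovered shares therefore do not give the power of the real comparisons, and a count of 0 calls cannot be read from them. The camera result likewise does not cover lists whose members vary together, such as the Kupffer cell list, with an estimated correlation of 0.835. A first simulation with a single unchanged list did not give every list its set result, and the simulation was then drawn again with 38.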

Results

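Gene expression was measured by RNA sequencing in the livers of 9 wild-type mice fed an AIN-93G diet, a purified and soy-free rodent feed, with 1 of 3 iron contents. The low-iron diet held 2.5 mg iron per kg, the sufficient diet 37.5 mg per kg and the high-iron diet 1000 mg per kg. Each diet was given to 3 separate mice for 50 days from 5 weeks of age, and livers were taken at 12 weeks. Hemojuvelin (Hjv) knockout mice, which the protocol also mentions, are not analysed here. Libraries are named by diet and by the number in their title. The low-iron libraries held 22 M (mega reads; replicate 1), 28.7 M (replicate 5) and 26.9 M (replicate 9) gene reads. The sufficient-iron libraries held 26 M (replicate 2), 33.8 M (replicate 6) and 30.8 M (replicate 10). The high-iron libraries held 25.9 M (replicate 4), 26.8 M (replicate 8) and 24 M (replicate 12).

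Rn45s, the 45S ribosomal RNA precursor, took 43.7% of the gene reads of low-iron replicate 1 and 40.5% of high-iron replicate 12, against 12.5% to 23.8% in the other 7 libraries. The Wilson 95% intervals of these shares, which cover counting error only, were at most 0.0415 percentage points wide. Lars2, whose read share followed that of Rn45s, took 3.47% to 11.6%. On principal components of log2 CPM, the first component (35.8% of the variance) set low-iron replicate 1 (-51.8) apart from sufficient-iron replicate 6 (41.2). The other low-iron libraries lay at -2.87 and 2.56, the other sufficient-iron libraries at 4.52 and 7.66 and the high-iron libraries at 0.668, -15 and 13.1, across both. The second component (18.3%) placed the high-iron libraries at -14.1, -25.5 and -26.5 and the other 6 at -1.04 or above. Within a diet, log2 CPM of replicate pairs correlated across genes at 0.973 to 0.989.

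The high-iron diet was compared with the sufficient diet to describe the response to dietary iron excess. Enzymes of fatty acid oxidation, a sterol exporter and a lipase rose in high-iron livers, and Nnmt, Alas2 and a pair of interferon-induced genes fell. Ehhadh, the bifunctional enzyme of peroxisomal fatty acid oxidation, rose from 346 ± 79.8 to 1150 ± 234 CPM (mean ± SD, n = 3 per diet), a log2 fold change of 1.74 ± 0.23 (SE; adjusted p = 0.0265). The fatty acid omega-hydroxylase gene Cyp4a10 rose from 175 ± 19.1 to 470 ± 107 CPM (1.43 ± 0.17, adjusted p = 0.0194), and the lipoprotein lipase gene Lpl from 22.9 ± 8.1 to 62.9 ± 8.79 CPM (1.45 ± 0.22, adjusted p = 0.0341). Krt23, a type I keratin gene, had the largest rise, from 1.81 ± 0.136 to 16.7 ± 3.52 CPM (3.21 ± 0.36, adjusted p = 0.0194).

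In all, 28 of 13020 tested genes changed, 13 higher and 15 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), with 1208 at an unadjusted p under 0.05. Abcg8 and Abcg5, which together form the sterol exporter of the bile canaliculus, rose by 1.19 (adjusted p = 0.0331) and 1.06 (0.0341) on the log2 scale. Smad9, a SMAD protein gene induced by BMP signalling, rose from 8.78 ± 1.1 to 28.7 ± 4.69 CPM (1.71 ± 0.26, adjusted p = 0.0341). Gsta2 (1.47), the imprinted gene Peg3 (1.29) and Hsd17b11 (1.02), which encodes a lipid-droplet dehydrogenase, also rose. Nnmt, the nicotinamide N-methyltransferase gene, fell by 2.40 ± 0.28 on the log2 scale, from 34.2 ± 2.04 to 6.54 ± 2.32 CPM (adjusted p = 0.0194). Mmd2 (-4.17) and the calcium pump gene Atp2b2 (-3.23) had larger falls from low levels, 7.07 ± 4.54 and 5.7 ± 2.51 CPM. Mmd2 stood at 12.3 CPM in sufficient-iron replicate 6 against 4.08 and 4.83 CPM in replicates 2 and 10. Its log2 fold change ran from -4.61 to -3.5 over the alternatives. Rsad2 (-1.94) and Cmpk2 (-1.31), both induced by interferon, and Stap1 (-1.83), Acnat2 (-1.81) and Sdr9c7 (-1.32) fell too. The prolactin receptor gene Prlr fell by 1.10 (adjusted p = 0.0381). Alas2, the erythroid form of the first enzyme of haem synthesis, fell from 71 ± 9.75 to 34.1 ± 5.33 CPM (-1.06 ± 0.17, adjusted p = 0.0479). The erythroid and blood marker list to which it belongs, with 5 tested members, was not past the test (camera adjusted p = 0.726). Between the high-iron and the low-iron diet that list was lower and past fry (adjusted p = 0.0164) but not past camera (0.145). Without high-iron replicate 4 or high-iron replicate 8 the count was 0, and it was 8 without high-iron replicate 12. It was 18 without sufficient-iron replicate 2, 13 without replicate 6 and 4 without replicate 10 of that diet, and 56, 16 and 11 without low-iron replicates 1, 5 and 9, while DESeq2 called 218.

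**Figure D1:**
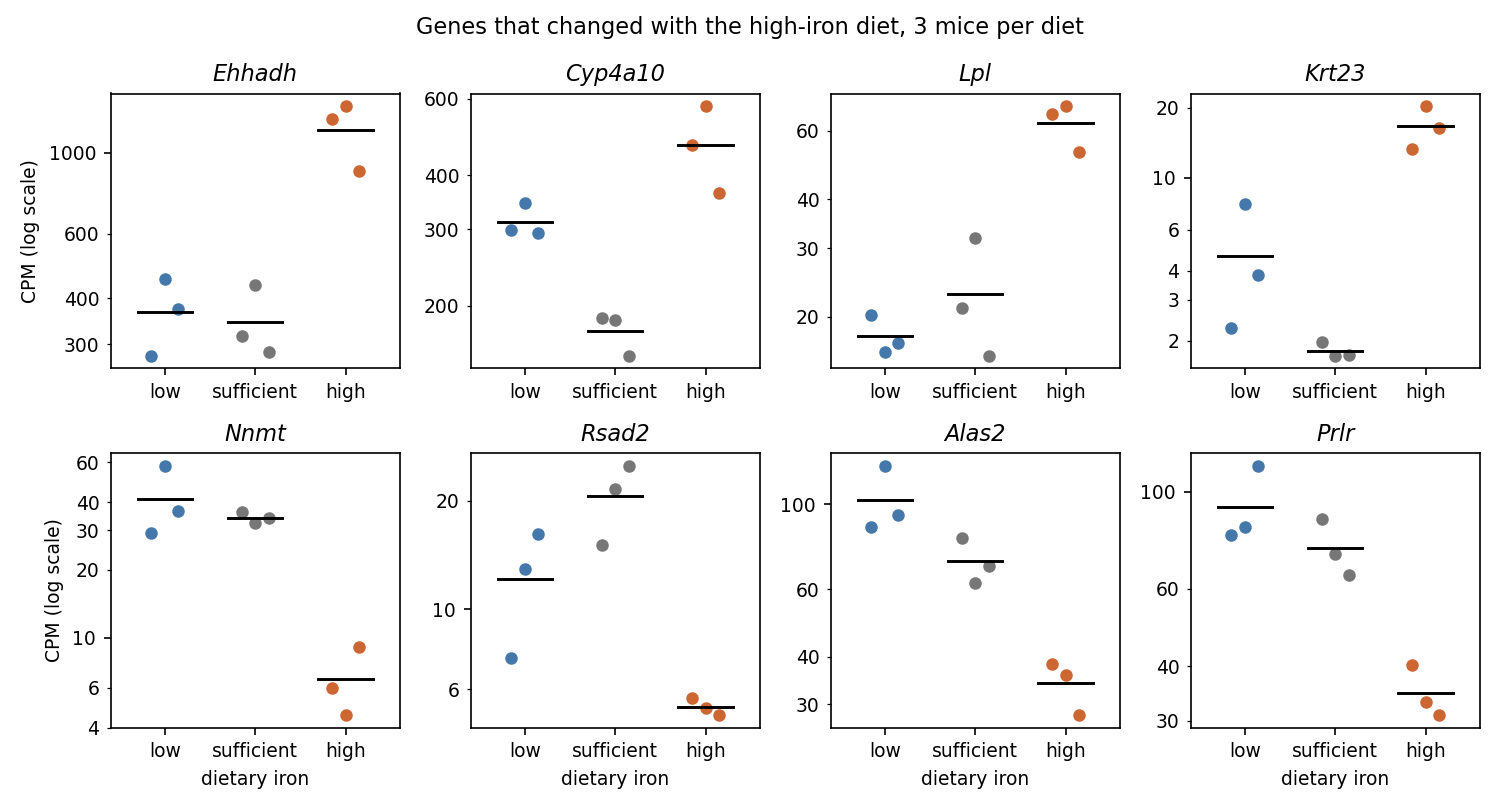
CPM on a log axis of 8 genes that changed between the high-iron and the sufficient diet, 1 point per mouse and a black line at the mean of each diet (n = 3). Ehhadh, Cyp4a10, Lpl and Krt23 were higher in all 3 high-iron mice than in the 3 sufficient-iron mice, and Nnmt, Rsad2, Alas2 and Prlr were lower.

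By gene list, 14 of 39 lists were past the camera test, 7 in each direction, and 0 of them remained past it with an estimated correlation. Of 33 tested genes of fatty acid oxidation and PPAR-alpha targets, 3 rose over all genes tested (Cyp4a10, Ehhadh and Acaa1b), and adjusted over the list alone 11 rose and 1 fell. The list rose with a median log2 fold change of 0.23 (camera adjusted p = 1.41e-09; adjusted p = 0.429 with an estimated correlation). Among 33 NRF2 targets, genes of glutathione and redox metabolism, Gsta2 rose over all genes and 8 rose adjusted over the list alone (median 0.25, adjusted p = 1.58e-06; adjusted p = 0.429 with an estimated correlation). The transporter gene Abcc3 (0.72, adjusted p = 0.058) and Gstm1 (1.56, adjusted p = 0.0898) stayed above the threshold over all genes. The BMP-SMAD iron-sensing targets rose as a list, with positive values for 12 of 12 members (median 0.71, adjusted p = 3.2e-06; adjusted p = 0.429 with an estimated correlation). Smad9 alone among them rose over all genes, and 2 rose adjusted over the list alone. Cholesterol synthesis genes rose as a list with 0 members past the test (25 tested, median 0.27, adjusted p = 6.24e-05; adjusted p = 0.689 with an estimated correlation). Nuclear subunits of oxidative phosphorylation also rose (31 tested, 0 past the test, median 0.23, adjusted p = 2.7e-05; adjusted p = 0.684 with an estimated correlation). Iron-sulfur cluster assembly genes rose (22 tested, 0 past the test, median 0.23, adjusted p = 0.000881; adjusted p = 0.684 with an estimated correlation), a call lost without high-iron replicate 8 (0.0503).

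The interferon response list fell, with negative values for 29 of 29 members (median -0.85, camera adjusted p = 3.85e-14; adjusted p = 0.577 with an estimated correlation). Relative to the mean of the 9 libraries, its median log2 CPM was -0.037, 0.564 and 0.922 in sufficient-iron replicates 2, 6 and 10. It was -0.574, -0.237 and -0.057 in high-iron replicates 4, 8 and 12, and -0.396, -0.316 and 0.378 in low-iron replicates 1, 5 and 9. Rsad2 fell over all genes and 16 members fell adjusted over the list alone, and Ifit1 (-1.88, adjusted p = 0.0634) and Isg15 (-1.27, adjusted p = 0.0854) stayed above the threshold over all genes. Of 25 acute phase genes 0 changed over all genes, and adjusted over the list alone 8 fell and 1 rose (median -0.41, adjusted p = 2.35e-06; adjusted p = 0.429 with an estimated correlation). The acute phase gene Orm2 had a log2 fold change of -1.28 (adjusted p = 0.245). Kupffer cell and macrophage markers fell beside them (17 tested, 0 past the test, median -0.49, adjusted p = 0.000293; adjusted p = 0.689 with an estimated correlation). Cell cycle genes fell (27 tested, 0 past the test, median -0.73, adjusted p = 1.43e-05; adjusted p = 0.689 with an estimated correlation), a call lost without sufficient-iron replicate 6 (0.327). Monocyte and neutrophil markers fell (9 tested, 0 past the test, median -0.58, adjusted p = 0.0395; adjusted p = 0.689 with an estimated correlation). Their call was lost without sufficient-iron replicate 6 (0.126) or 10 (0.131) and without high-iron replicate 4 (0.216) or 8 (0.0967). Unfolded protein response genes fell (20 tested, 0 past the test, median -0.23, adjusted p = 0.0307; adjusted p = 0.804 with an estimated correlation). That call was lost without sufficient-iron replicate 2 (0.206) or 6 (0.0523) or high-iron replicate 12 (0.607). Adipocyte markers rose (7 tested, median 1.45, adjusted p = 0.0174; adjusted p = 0.429 with an estimated correlation), with Lpl past the test over all genes and 4 higher and 1 lower adjusted over the list alone. The call was lost without sufficient-iron replicate 10 (0.0569). Krt23 is also on the cholangiocyte list, which was not past the test (adjusted p = 0.262) except without high-iron replicate 8 (0.00945).

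Of the iron panel, 0 of 14 genes passed the edgeR test between the high-iron and the sufficient diet, and 5 had an unadjusted p under 0.05. Hamp, which encodes hepcidin, the hormone that lowers iron release into plasma, stood at 715 ± 212 against 199 ± 72.2 CPM (1.85 ± 0.76, adjusted p = 0.517). Its paralog Hamp2 stood at 131 ± 20.1 against 44.2 ± 11.3 CPM (1.57 ± 0.65, adjusted p = 0.517). Atoh8 had a log2 fold change of 1.22 (adjusted p = 0.294), the iron importer gene Slc11a2 one of -0.54 (0.245) and the transferrin receptor gene Tfrc one of -0.97 (0.532). Bmp6 (adjusted p = 0.679), Id1 (0.555), Smad7 (0.544), Tfr2 (0.696) and Hmox1 (0.753) did not pass either. Hamp2 passed in 5 of 21 alternatives (adjusted p = 0.00454 to 0.998), 1 of them without low-iron replicate 1 (0.0167), and Atoh8 in 1 of 22, DESeq2 (0.0459 to 0.944). Ferritin genes Fth1 (0.24, adjusted p = 0.635) and Ftl1 (0.44, adjusted p = 0.59), the exporter gene Slc40a1 (-0.12, adjusted p = 0.861) and Hjv, named Hfe2 in the files (-0.07, adjusted p = 0.905), differed by less than 2 SE. The list of iron uptake, storage and export genes fell (27 tested, 0 past the test, 1 lower adjusted over the list alone, median -0.13, adjusted p = 0.0174; adjusted p = 0.596 with an estimated correlation). Its call was lost without sufficient-iron replicate 6 (0.058) or high-iron replicate 12 (0.0537).

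The low-iron diet was compared with the sufficient diet to describe the response to iron deficiency. Hamp and its fellow BMP-SMAD targets were lower as a list in low-iron livers, drug-metabolising cytochromes P450 and genes of oxidative phosphorylation were higher as lists, and interferon response genes were lower as a list, while no single gene passed the test. With an estimated correlation 0 of these list calls remained (lowest adjusted p = 0.0908, for the cytochromes P450). Hamp stood at 9.09 ± 11.2 CPM in low-iron livers against 199 ± 72.2 CPM in sufficient-iron livers (n = 3 per diet; log2 fold change -4.55 ± 0.88, adjusted p = 0.446), at 21.8, 0.805 and 4.62 CPM in the low-iron mice, and without low-iron replicate 1 the log2 fold change was -6.20. Over the alternatives its adjusted p ran from 0.000207 to 0.835, past the test in 2 of 22. Of 13020 genes 0 passed in edgeR quasi-likelihood and 1458 had an unadjusted p under 0.05. DESeq2 called 105 genes (101 higher and 4 lower in low iron), limma-voom 0, and limma-voom with sample quality weights 2, Hamp and Hamp2. Without low-iron replicate 1, Hamp2 alone passed, and its log2 fold change moved from -1.32 to -2.90. Genes with the lowest p were the carboxylesterase genes Ces1e (0.58 ± 0.11) and Ces2a (0.62 ± 0.12) and the glutathione transferase gene Gstk1 (0.75 ± 0.15) on the higher side, each at an adjusted p of 0.446. On the lower side they were, beside Hamp, the kinase gene Map3k13 (-0.95 ± 0.19) and the cyclin D1 gene Ccnd1, at 18.2 ± 4.58 against 48 ± 21.9 CPM, at the same adjusted p. Of the iron panel, Tfrc stood at 70 ± 35 against 26.9 ± 12.6 CPM (1.39 ± 0.41, adjusted p = 0.446). Id1 (-2.31), Atoh8 (-1.34), Slc11a2 (0.35) and Hmox1 (-0.40) had the same adjusted p. Fth1 (0.33, adjusted p = 0.45), Tfr2 (0.21, 0.486), Ftl1 (0.30, 0.58), Slc40a1 (-0.23, 0.642) and Hfe2 (0.15, 0.75) did not pass either.

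Of 39 lists, 21 were past the camera test, 12 higher and 9 lower, and 0 remained past it with an estimated correlation. The BMP-SMAD targets fell as a list, with negative values for 12 of 12 members, 10 of which fell adjusted over the list alone (median -1.16, camera adjusted p = 1.87e-09; adjusted p = 0.327 with an estimated correlation). Bmp6, the ligand gene upstream of hepcidin, stood at 2.1 ± 0.279 against 4.15 ± 0.927 CPM. Id3 had a log2 fold change of -1.42 ± 0.37 and Smad7 one of -1.38 ± 0.39, all 3 genes with an adjusted p of 0.446 over all genes. Drug-metabolising cytochromes P450 rose as a list, with 13 of 23 members higher adjusted over the list alone, Cyp2a12 (0.45), Cyp1a2 (0.75), Cyp3a25 (0.44) and Cyp2d10 (0.57) among them (median 0.45, adjusted p = 3.91e-08; adjusted p = 0.0908 with an estimated correlation; fry adjusted p = 0.0257). Pericentral hepatocyte markers rose beside them, with 6 of 14 higher adjusted over the list alone (median 0.42, adjusted p = 4.76e-06; adjusted p = 0.327 with an estimated correlation). All 31 oxidative phosphorylation genes had positive values and 0 passed adjusted over the list alone (median 0.43, adjusted p = 1.01e-10; adjusted p = 0.357 with an estimated correlation), with Sdhb at 0.63 and Ndufa9 at 0.37. Haem synthesis genes rose as a list (18 tested, median 0.22, adjusted p = 0.00151; adjusted p = 0.368 with an estimated correlation), with Alas2 at 0.53 (adjusted p = 0.446). Iron-sulfur cluster assembly (22 tested, median 0.25, adjusted p = 0.000947; adjusted p = 0.473 with an estimated correlation) rose as well, as did the glutathione peroxidase and superoxide dismutase list (19 tested, median 0.20, adjusted p = 0.0043; adjusted p = 0.368 with an estimated correlation). In these last 3 lists 0 members passed over all genes or adjusted over the list alone. The oxidative phosphorylation median stood at 0.537 log2 CPM in low-iron replicate 1, the library richest in Rn45s, against -0.005 and 0.113 in the other low-iron mice, and at -0.354 in sufficient-iron replicate 6. Without these 2 libraries the adjusted p was 1.28e-07 for oxidative phosphorylation, 0.024 for haem synthesis and 0.143 for iron-sulfur cluster assembly, whose call was then lost. Each library's log2 CPM relative to the mean had a trend with transcript length. Its Spearman rho was -0.232, 0.0596 and -0.0435 in low-iron replicates 1, 5 and 9. It was 0.137, 0.205 and 0.151 in sufficient-iron replicates 2, 6 and 10, and 0.0247, -0.247 and 0.144 in high-iron replicates 4, 8 and 12. High-iron replicate 8, with the lowest rho, had an oxidative phosphorylation median of 0.199. The part of this trend in the calls of these lists was not tested in any comparison.

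The interferon response list fell (median -0.62, negative in 29 of 29, 0 past the test; camera adjusted p = 8.93e-09; adjusted p = 0.473 with an estimated correlation), with Oas2 at -1.04 and Irf7 at -0.68. Kupffer cell and macrophage markers fell beside it, with 2 of 17 lower adjusted over the list alone (median -0.68, adjusted p = 8.93e-09; adjusted p = 0.429 with an estimated correlation), with Marco at -2.55 ± 0.55. Monocyte and neutrophil markers fell as well (9 tested, 0 past the test, median -0.59, adjusted p = 0.00143; adjusted p = 0.373 with an estimated correlation). In low-iron replicate 1 their medians stood at -1.10 and -0.75 log2 CPM relative to the mean of the 9 libraries. Cell cycle genes fell as a list, with 1 of 27, Ccnd1, lower adjusted over the list alone (median -0.86, adjusted p = 3.27e-05; adjusted p = 0.531 with an estimated correlation). Extracellular matrix genes fell too (24 tested, 0 past the test, median -0.65, adjusted p = 9.3e-05; adjusted p = 0.531 with an estimated correlation). Both calls were lost without sufficient-iron replicate 6 (0.213 and 0.336). Male-biased growth hormone-dependent genes rose as a list (20 tested, 0 past the test, median 0.55, adjusted p = 0.000658; adjusted p = 0.507 with an estimated correlation), a call also lost without that library (0.0783). Endothelial markers (18 tested, median -0.31, adjusted p = 0.000855; adjusted p = 0.531 with an estimated correlation) fell with a call lost without low-iron replicate 1 (0.2). Stellate cell markers (16 tested, median -0.33, adjusted p = 0.00624; adjusted p = 0.531 with an estimated correlation) fell with a call lost without low-iron replicate 1 (0.0691) or sufficient-iron replicate 6 (0.229).

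Smaller shifts of lists in low-iron livers had calls that were lost when 1 or another library was left out. Fatty acid oxidation genes (33 tested, 1 higher adjusted over the list alone, median 0.15, camera adjusted p = 0.000855; adjusted p = 0.507 with an estimated correlation) rose, with Cyp4a10 at 0.84, but not without low-iron replicate 9 (0.0561) or sufficient-iron replicate 2 (0.0556). Bile acid genes (22 tested, 0 past the test, median 0.18, adjusted p = 0.00604; adjusted p = 0.357 with an estimated correlation) rose, but not without low-iron replicate 5 (0.0731). Gluconeogenesis and glycolysis genes (22 tested, 0 past the test, median 0.12, adjusted p = 0.0122; adjusted p = 0.368 with an estimated correlation) rose, but not without low-iron replicate 5 (0.0731) or sufficient-iron replicate 10 (0.108). Periportal markers (13 tested, 2 higher adjusted over the list alone, median 0.32, adjusted p = 0.00214; adjusted p = 0.473 with an estimated correlation) rose, but not without low-iron replicate 5 (0.121) or sufficient-iron replicate 10 (0.108). Cholangiocyte markers (11 tested, median -0.46, adjusted p = 0.0316; adjusted p = 0.507 with an estimated correlation) fell as a list while Krt23 was higher adjusted over the list alone. The call was lost without low-iron replicate 1 (0.2) or 9 (0.126) or sufficient-iron replicate 6 (0.0882) or 10 (0.179). Adipocyte markers (7 tested, 1 higher adjusted over the list alone, median 0.42, adjusted p = 0.039; adjusted p = 0.357 with an estimated correlation) rose, but not without low-iron replicates 1 (0.0573), 5 (0.0606) or 9 (0.0617) or sufficient-iron replicates 2 (0.0598) or 10 (0.13).

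Both comparisons use the same 3 sufficient-iron libraries, which alone makes their fold changes correlate. Across the 13020 genes, which are not independent replicates, the fold changes of high and of low iron against the sufficient diet correlated at 0.466, against 0.463 ± 0.0112 (SD) in 100 simulations of unchanged groups with a shared reference. Their covariance was 0.0562 against 0.0337 ± 0.00109 in the simulations. The simulations drew each gene independently and left out variation that many genes of a library share. The gap in covariance therefore does not show a response shared by both diets. Camera called several lists in the same direction in both comparisons. Interferon, Kupffer cell, monocyte and cell cycle lists were lower. Oxidative phosphorylation, iron-sulfur cluster, fatty acid oxidation and adipocyte lists were higher. Such calls are not separate evidence for each diet, because of the shared libraries. Between the high-iron and the low-iron diet, camera called the oxidative phosphorylation, fatty acid oxidation and Kupffer cell lists. It did not call the iron-sulfur cluster (adjusted p = 0.854), cell cycle (0.854), monocyte (0.275) or adipocyte (0.678) list there. The interferon response list had a median of -0.11 there and was not past the test (camera adjusted p = 0.0607, and 0.859 with an estimated correlation). It was lower and past it without low-iron replicates 1 (0.00245) or 5 (0.0143), sufficient-iron replicates 2 (0.0264) or 10 (0.0299) or high-iron replicates 8 (0.0263) or 12 (0.00975). Without low-iron replicate 9 it was higher and not past it (0.848). With the title number as a covariate the list had a camera adjusted p of 5.57e-11.

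The high-iron and the low-iron diet, the ends of the dietary range, were compared to describe the full span of the response to iron. Hepcidin and other genes of the BMP-SMAD pathway, which senses body iron in the liver, were far higher in high-iron livers, and the iron importer gene Slc11a2 and Alas2 were lower. Hamp rose from 9.09 ± 11.2 to 715 ± 212 CPM (mean ± SD, n = 3 per diet), an 84.2-fold rise (log2 6.40 ± 0.95, adjusted p = 0.029; 1.91e-09 to 0.108 over the alternatives). The size rests on low-iron replicate 1, at 21.8 CPM against 0.805 and 4.62 CPM, without which the log2 fold change was 8.04. The call of Hamp was lost without low-iron replicate 9 (0.106) and without high-iron replicates 4 (0.0886), 8 (0.0855) or 12 (0.0673). Atoh8, a transcription factor gene that responds to BMP signals, rose from 5.97 ± 1.6 to 34.4 ± 13.8 CPM (2.56 ± 0.39, adjusted p = 0.0246). Smad9 rose by 2.43 ± 0.28 (adjusted p = 0.0113), the inhibitory SMAD gene Smad7 by 2.15 ± 0.39 (adjusted p = 0.045) and Bmp6 by 1.27 ± 0.22 (adjusted p = 0.0359). Slc11a2 fell from 35.4 ± 4.15 to 19.1 ± 3.25 CPM (-0.89 ± 0.15, adjusted p = 0.0328), and Alas2 from 102 ± 20.9 to 34.1 ± 5.33 CPM (-1.58 ± 0.18, adjusted p = 0.0113). Bmp6 was no longer past the test without low-iron replicates 5 (0.137) or 9 (0.15) or high-iron replicates 4 (0.163), 8 (0.0855) or 12 (0.127). Atoh8 lost its call without low-iron replicates 1 (0.0649), 5 (0.106) or 9 (0.101) or high-iron replicates 4 (0.0886) or 8 (0.0855). Slc11a2 lost it without low-iron replicates 5 (0.113) or 9 (0.0804) or high-iron replicates 4 (0.0719), 8 (0.15) or 12 (0.127). For Smad7 it was lost without low-iron replicates 1 (0.119), 5 (0.173) or 9 (0.16), sufficient-iron replicate 2 (0.0574) or high-iron replicates 4 (0.111), 8 (0.161) or 12 (0.125). In the GENCODE M21 annotation Hamp lies on chromosome 7 from 30942368 to 30944032 and Hamp2 from 30922372 to 30924681, both protein-coding genes on the minus strand, while the build behind the counts is not settled by the processing notes.

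In all 66 genes changed, 21 higher and 45 lower (edgeR quasi-likelihood, adjusted p under 0.05), with 1257 at an unadjusted p under 0.05. Peg3 rose by 2.19 ± 0.23 (adjusted p = 0.0113), the transporter gene Abcc4 by 1.86 ± 0.30 (adjusted p = 0.0313), and Lpl by 1.82 ± 0.23 (adjusted p = 0.0125). Ehhadh rose by 1.65 ± 0.23 (adjusted p = 0.0172) and Serpinb6b by 1.11 ± 0.19 (adjusted p = 0.0347). Nnmt fell from 41.3 ± 15 to 6.54 ± 2.32 CPM (-2.69 ± 0.29, adjusted p = 0.0113). Mmd2 (-3.94), Wfdc2 (-3.02), Atp2b2 (-2.40), the membrane carbonic anhydrase gene Car14 (-1.90) and Hapln4 (-1.81) fell, as did Acnat2 (-1.75), the magnesium transporter gene Slc41a2 (-1.70) and Sdr9c7 (-1.66). Of the iron panel, Hamp, Bmp6, Smad7, Atoh8 and Slc11a2 passed. Tfrc (-2.35 ± 0.43, adjusted p = 0.0506), Id1 (3.56 ± 0.71, adjusted p = 0.0646) and Hamp2 (2.89 ± 0.69, adjusted p = 0.12) did not pass. Among the alternatives Tfrc passed in 7 of 22 (adjusted p = 1.31e-06 to 0.256), Id1 in 5 of 22 (0.000345 to 0.321) and Hamp2 in 5 of 21 (1.35e-06 to 0.367). With single libraries left out, Tfrc passed without sufficient-iron replicates 2 (0.0488) or 10 (0.0236), Id1 without sufficient-iron replicates 2 (0.0488), 6 (0.0429) or 10 (0.0162), and Hamp2 without low-iron replicate 1 (0.000202), where its log2 fold change was 4.47. Tfr2 had a log2 fold change of -0.35 (adjusted p = 0.293; 0.0296 to 0.635 over the alternatives), Fth1 -0.09 (0.898), Ftl1 0.14 (0.891), Slc40a1 0.11 (0.905), Hmox1 0.24 (0.728) and Hfe2 -0.22 (0.774). Without high-iron replicate 8 the count was 0, without high-iron replicate 4 it was 1 and without high-iron replicate 12 it was 13. It was 106, 23 and 6 without low-iron replicates 1, 5 and 9 and 112 without sufficient-iron replicate 6, while DESeq2 called 365 genes and limma-voom 64.

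**Figure D2:**
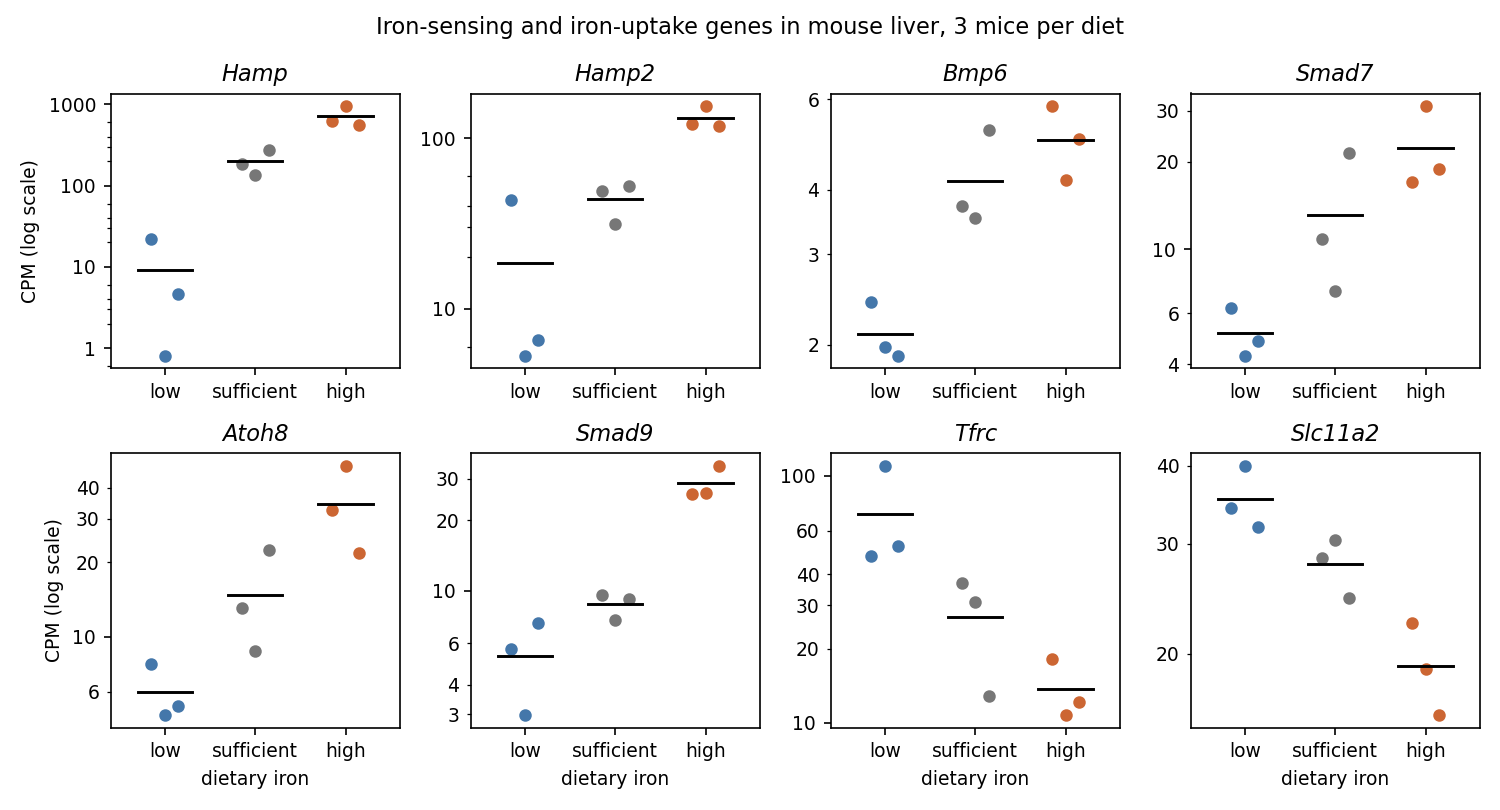
CPM on a log axis of 8 genes of iron sensing and iron uptake, 1 point per mouse and a black line at the mean of each diet (n = 3). Hamp ran from 0.805 to 21.8 CPM in low-iron mice and from 563 to 957 CPM in high-iron mice.

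Of 39 lists, 16 were past the camera test, 8 in each direction, and 0 remained past it with an estimated correlation. All 12 BMP-SMAD targets rose adjusted over the list alone and 5 over all genes (median 1.93, camera adjusted p = 2e-18; adjusted p = 0.0857 with an estimated correlation; fry adjusted p = 0.0078). Drug-metabolising cytochromes P450 fell as a list, with Cyp2a12 (-0.71, adjusted p = 0.0313) and Cyp2c38 (-0.85, adjusted p = 0.0331) past the test over all genes. Adjusted over the list alone 9 of 23 were lower (median -0.50, adjusted p = 1.31e-07; adjusted p = 0.0857 with an estimated correlation; fry adjusted p = 0.0078). Pericentral hepatocyte markers fell, with the ammonium transporter gene Rhbg (-1.51, adjusted p = 0.0191) and the ornithine aminotransferase gene Oat (-1.14, adjusted p = 0.0328) past the test over all genes. Adjusted over the list alone 7 of 14 were lower (median -0.39, adjusted p = 1e-06; adjusted p = 0.237 with an estimated correlation). Periportal markers fell too, with the urea cycle gene Asl (-0.82, adjusted p = 0.0328) past the test and 3 of 13 lower adjusted over the list alone (median -0.28, adjusted p = 0.000845; adjusted p = 0.524 with an estimated correlation). Among 25 acute phase genes, Crp (-0.67, adjusted p = 0.029) and Itih4 (-1.03, adjusted p = 0.0328) fell over all genes and 5 fell adjusted over the list alone (median -0.41, adjusted p = 2.94e-06; adjusted p = 0.353 with an estimated correlation). The bile acid list fell, with 8 members lower and 2 higher of 22 adjusted over the list alone and Abcg8 (0.97, adjusted p = 0.0339) the one past the test over all genes (median -0.26, adjusted p = 0.00139; adjusted p = 0.272 with an estimated correlation). Male-biased genes fell, with 5 of 20 lower adjusted over the list alone and 0 over all genes (median -0.43, adjusted p = 0.00108; adjusted p = 0.77 with an estimated correlation). Pklr (-1.10, adjusted p = 0.0432), a glycolytic enzyme gene on the lipid synthesis list, and the carbonic anhydrase gene Car3 (-1.25, adjusted p = 0.0125) fell.

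NRF2 targets rose, with Abcc4 and Gstm4 (0.80, adjusted p = 0.0339) past the test and 6 higher and 1 lower of 33 adjusted over the list alone (median 0.29, camera adjusted p = 0.000255; adjusted p = 0.524 with an estimated correlation). Cholesterol synthesis genes rose, 5 of 25 adjusted over the list alone and 0 over all genes, with Hsd17b7 at 0.70 and Idi1 at 0.81 (median 0.31, adjusted p = 1.95e-06; adjusted p = 0.704 with an estimated correlation). Cholangiocyte markers rose, with 1 of 11, Krt23 (1.81, adjusted p = 0.0507), higher adjusted over the list alone (median 0.67, adjusted p = 0.000255; adjusted p = 0.432 with an estimated correlation). Fatty acid oxidation genes rose, with Ehhadh past the test and 9 of 33 higher adjusted over the list alone (median 0.09, adjusted p = 0.00428; adjusted p = 0.77 with an estimated correlation), a call lost without low-iron replicate 1 (0.196) or high-iron replicate 8 (0.0903). Oxidative phosphorylation genes fell (31 tested, 0 past the test, median -0.16, adjusted p = 0.00363; adjusted p = 0.77 with an estimated correlation), a call lost without low-iron replicate 1 (0.22) or high-iron replicate 12 (0.152). Unfolded protein response genes fell (20 tested, 1 lower adjusted over the list alone, median -0.19, adjusted p = 0.00951; adjusted p = 0.77 with an estimated correlation), a call lost without low-iron replicate 5 (0.332) or high-iron replicate 12 (0.334). Extracellular matrix genes (24 tested, median 0.33, adjusted p = 0.00993), endothelial markers (18 tested, median 0.23, adjusted p = 0.00379) and Kupffer cell markers (17 tested, median 0.20, adjusted p = 0.00613) rose with 0 members past the test, each with an adjusted p = 0.78 with an estimated correlation. Without low-iron replicate 1 their adjusted p was 0.209, 0.617 and 0.617, the Kupffer list then being lower, and without high-iron replicate 12 it was 0.42, 0.152 and 0.12.

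**Figure D3:**
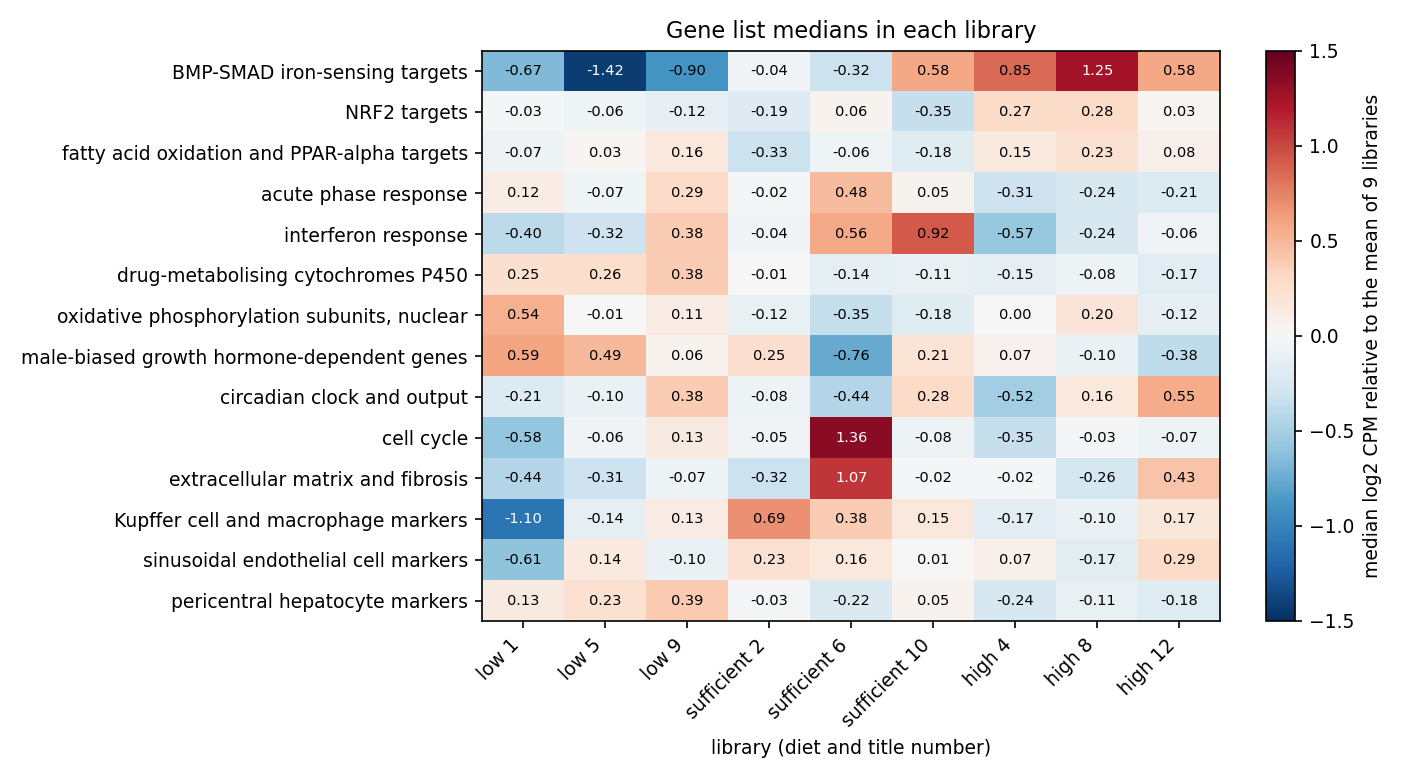
Median log2 CPM of 14 gene lists in each of the 9 libraries, relative to the mean of the 9 libraries, red where higher and blue where lower. The BMP-SMAD targets ran from -1.42 to -0.67 in low-iron libraries and from 0.58 to 1.25 in high-iron libraries, while cell cycle genes stood at 1.36 in sufficient-iron replicate 6 alone.

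Across all 3 diets, 28 genes changed in the 3-group test and 40 followed the log10 of dietary iron, 14 upward and 26 downward (edgeR quasi-likelihood, adjusted p under 0.05). The lowest p-values of the 3-group test belonged to Peg3, Smad9, Nnmt, Krt23 and Ehhadh, each with an adjusted p of 0.0221. Along the trend Peg3 rose by 0.85 ± 0.08 on the log2 scale per 10-fold iron (SE; adjusted p = 0.00687), from 2.00 through 3.70 to 9.09 CPM. Smad9 (0.95), Atoh8 (0.97), Lpl (0.72) and the neuropilin gene Nrp2 (0.35) rose as well. Alas2 fell by 0.61 ± 0.07 per 10-fold iron (adjusted p = 0.0107), and Car3 (-0.48), Igfals (-0.45), which encodes a carrier of IGF1, the vitronectin gene Vtn (-0.31) and the angiotensinogen gene Agt (-0.34) also fell. The 3-group count was 0 without high-iron replicate 4 or 8 and 5 without replicate 12, 68, 9 and 5 without low-iron replicates 1, 5 and 9, and 54 without sufficient-iron replicate 6. The trend count was 1, 2 and 0 without high-iron replicates 4, 8 and 12, 80, 15 and 3 without low-iron replicates 1, 5 and 9, and 24, 96 and 18 without sufficient-iron replicates 2, 6 and 10. With the title number as a covariate the trend count was 9, 8 of them among the 40. Consecutive title numbers as a block left a trend count of 14, 11 of them among the 40.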

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

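The title-number settings and the settings that leave out pairs of libraries or the genes Rn45s and Lars2 were chosen after seeing the data, and the other settings before. No paired analysis was possible because the title numbers are not shared between diets and the labels give no pairs, and the block of consecutive title numbers below is a grouping guessed from the titles. Counts are given in the order high against sufficient, low against sufficient, high against low, 3-group test and trend, where 28, 0, 66, 28 and 40 genes passed. The count of 0 for low against sufficient is from edgeR, with 1458 genes at an unadjusted p under 0.05 and 0 by limma-voom. DESeq2 size factors, upper-quartile scaling, a filter at 1 CPM, limma-voom, Rn45s and Lars2 left out and the 6 compared libraries alone moved each count that could be run by no more than 1.5 times. The genes behind a count could still differ. With the 6 compared libraries alone, 21 of the 28 genes of high against sufficient and 49 of the 66 of high against low kept their call.

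With each library left out in turn the counts ran from 0 to 56, 0 to 1, 0 to 112, 0 to 68 and 0 to 96. Without high-iron replicate 4 or 8 the fewest calls of named genes were kept, 1 and 0 of 41, where a gene called in both comparisons counts in each. At an adjusted p under 0.01 the counts were 0, 0, 0, 0 and 1, and under 0.1 they were 66, 0, 168, 96 and 119, as the threshold itself requires fewer or more. A log2 fold change of at least 1 left 40 genes of high against low. Without a filter on low counts 45 genes passed for high against sufficient and 52 in the 3-group test. DESeq2 gave 218, 105, 365, 413 and 313, and limma-voom with sample quality weights 92, 2, 378, 274 and 294. The title number as a covariate gave 58 for high against sufficient, 33 for high against low, 46 in the 3-group test and 9 for the trend. Consecutive title numbers as a block gave 40 for high against low, 32 of them among the 66, and 14 for the trend, 11 of them among the 40. For high against sufficient the block gave 32, 20 of them among the 28. Of the 41 calls of named genes 11 were lost with the block. Without the 2 libraries with the most 45S reads (low-iron replicate 1 and high-iron replicate 12) the counts were 17, 1, 31, 15 and 3, and without the 2 at the ends of the first component (low-iron replicate 1 and sufficient-iron replicate 6) they were 63, 1, 288, 192 and 257. Camera past the test on 14, 21 and 16 lists gave 0, 0 and 0 with an estimated correlation, and fry gave 1, 2 and 4. For high against sufficient the fry call was the adipocyte markers (adjusted p = 0.0361). For low against sufficient fry called the cytochromes P450 (0.0257) and adipocyte markers (0.0286). For high against low it called the BMP-SMAD targets (0.0078), cytochromes P450 (0.0078), erythroid and blood markers (0.0164) and pericentral markers (0.0344). The cause of these differences was not tested.

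Some panel genes with fold changes near 0 reversed direction, none past the test in any setting. Against the sufficient diet in high iron, Slc40a1 reversed with voom weights (adjusted p = 0.965), without the libraries at the component ends (0.998) and without sufficient-iron replicate 6 or high-iron replicate 8 (1 each; 0.685 to 1 over all settings), and Hfe2 without sufficient-iron replicate 10 (0.97; 0.817 to 0.998 with single libraries left out, 0.526 to 0.998 over all settings). Against it in low iron, Slc40a1 reversed with voom weights (0.985) and without the component ends (0.989; 0.386 to 0.989 over all settings), Ftl1 without low-iron replicate 1 (0.997) and without the ends (0.992; 0.41 to 0.997), and Hfe2 with voom weights (0.823), without the 45S-rich libraries (0.894), without the ends (0.77) and without low-iron replicate 1 (0.884) or sufficient-iron replicate 6 (0.998; 0.537 to 0.998). Between high and low iron, Slc40a1 reversed without the 45S-rich libraries (0.942), the ends (0.943), low-iron replicate 1 (0.968) or high-iron replicate 4 (0.994; 0.639 to 0.994). Fth1 reversed without the 45S-rich libraries (0.792), the ends (0.915), low-iron replicate 1 (0.93) or high-iron replicate 12 (0.997; 0.749 to 0.999). Ftl1 reversed without low-iron replicate 5 (0.979) or high-iron replicate 8 (0.988; 0.417 to 0.988 with single libraries left out, 0.18 to 0.988 over all settings), and Hfe2 without the 45S-rich libraries (0.941), the ends (0.961) or low-iron replicate 1 (0.967; 0.643 to 0.976). The cause was not tested.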

Other observations

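The tests of the clock genes and of the share of 45S reads and of cell types on the first component were chosen only after those results were seen, as were the alternatives with title numbers and with pairs of libraries left out. Some gene groups did not pass the camera test in any of the 3 pairwise comparisons, which does not show that they were unchanged. The hepcidin regulators, such as Tfr2, Bmp2 and Smad5, had camera adjusted p-values of 0.671, 0.569 and 0.935 (high against sufficient, low against sufficient and high against low iron), with 0 of 17 members past the edgeR test in each. Targets of hypoxia-inducible factor, such as Egln3 and Bnip3, had 0.231, 0.465 and 0.827, and p53 targets, such as Cdkn1a and Fas, 0.231, 0.465 and 0.699. T and natural killer cell markers had 0.593, 0.421 and 0.854, and between low and sufficient iron passed, lower in low iron, only without low-iron replicate 9 (0.0216).

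Circadian clock genes differed more between mice of one diet than between diets. Dbp, a clock output gene, stood at 5.38, 7.76 and 32.7 CPM in low-iron replicates 1, 5 and 9, at 5.39, 5.66 and 27.1 CPM in sufficient-iron replicates 2, 6 and 10, and at 7.69, 30.8 and 45.5 CPM in high-iron replicates 4, 8 and 12. The first component of the 21 clock genes held 83.2% of its variance within diets, which argues against diet as its whole cause. It followed the title number over the 9 libraries (Spearman rho 0.933, exact permutation p = 0.00075; Pearson r 0.926, exact permutation p = 0.000284; r 0.887 without the 2 farthest libraries; 1 relation computed, two-sided). Title numbers may follow the order of harvest and thereby the time of day, but the labels give no time, and the meaning of the numbers stays open.

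Low-iron replicate 1 and sufficient-iron replicate 6 stood at opposite ends of the first component of all genes. Removal of each library's trend with transcript length left 97.5% of their distance, which argues against such a trend as the whole cause of that distance. The distance covers all genes with a known length, not the component alone. Length trends of these libraries ran in opposite directions (Spearman rho -0.232 in low-iron replicate 1 and 0.205 in sufficient-iron replicate 6). A part of the trend in the component stays open. The male-biased genes were 1.34 lower in sufficient-iron replicate 6, a difference of -1.14 log2 from that of zonal hepatocyte markers, while Kupffer (1.52), stellate (0.925) and cholangiocyte markers (0.965) and cell cycle genes (1.91) were higher there. Co-regulated genes in 1 library against 1 give no valid p, so the part of a lower share of hepatocytes stays open. The share of 45S reads correlated with the component at a Spearman rho of 0.317 (exact permutation p = 0.41; Pearson r 0.548, exact permutation p = 0.149; r 0.415 without the 2 farthest libraries), too few libraries to tell its part. An earlier test by the place of high-iron replicate 12, which lay 64.8 from low-iron replicate 1 and 28.1 from sufficient-iron replicate 6, was set aside because 1 library excludes nothing, and no effect of diet was tested as a cause of this pattern.

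The 66 genes that changed between the high-iron and the low-iron diet kept a median of 98% of their log2 fold change (quartiles 93.9% to 102%) with the title number as a covariate, all 66 with the same sign. Title numbers are interleaved over the diets, so a strong linear trend with them would widen the spread within each diet. Genes called for a difference between diets therefore had to keep most of it. The 98% thus adds no evidence against such a trend beyond the calls themselves. Of the 66 genes, 27 still passed with this covariate, with standard errors 1.06 times as large. With each library's length trend removed they kept 99.5% at the median (quartiles 98.9% to 101%) and 63 still passed, which argues against that trend. A hypothesis of this work is that most of the change lies above the sufficient iron level: 47 of the 66 genes (71.2%) had a steeper slope per log10 iron there (exact binomial p = 0.000756 against an even split, on genes that are not independent and share the 3 sufficient-iron libraries; 43.6% of all tested genes did), a number that ran from 42 without sufficient-iron replicate 2 to 52 without replicate 10. All 8 genes with a bend past the test (Atp2b2, Mmd2, Acnat2, Hsd17b11, Abcg8, Ehhadh, Nnmt and Pter) bent that way, while Hamp made 28.9%, Bmp6 21.2% and Smad7 35.8% of their change above the sufficient level, whose step is 54.8% of the range in log10 iron.

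For each pair of diets the 10 splits of 6 libraries are too few for a share under 0.05. Between the high-iron and the sufficient diet the real split gave 28 genes and the highest other split 1, so that 1 of 10 splits gave as many. Between the high-iron and the low-iron diet the real split gave 66 and the highest other 0, so that 1 of 10 gave as many. Between the low-iron and the sufficient diet the real split gave 0 genes in edgeR (1458 at an unadjusted p under 0.05; DESeq2 105, limma-voom 0), the highest other 0, so that 10 of 10 gave as many. For the trend 1 of 100 splits gave as many as the real 40, with 13 in the highest other. For the 3-group test 2 of 100 gave as many as the real 28. Both shares lie under 0.05, which argues against chance but does not exclude it. In the 3-group test the other of the 2 splits gave 39 genes, more than the real one. It kept the 3 high-iron libraries together while exchanging low-iron replicate 9 with sufficient-iron replicate 2. The 3-group count therefore does not tell the low-iron from the sufficient diet.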
